A study of Homo sapiens with 33 samples.

How the data were processed

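Total RNA from 33 human skin biopsies was labelled with biotin and hybridised to Affymetrix expression arrays, per the labels' protocols. The deposited table holds 1 log2 value per probe set and array, made by the authors with GCRMA, per the submitters' processing notes, in a version that is not given in the sources used here. GCRMA corrects background with a model of probe sequence, normalizes between arrays by quantiles and summarises the probes of a set on the log2 scale. It also leaves a floor, at a log2 value of 2.09 in these data, where between 25.5% and 28.2% of the probe sets of each array lie. Values at the floor have no order, and folds against them are understated. Where every array of a group lay at or below a log2 value of 3, the fold is therefore given as a bound, from the mean of the other group and a level of 3 for the low group, with limma's adjusted p.

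Groups were taken from the disease state in the labels, giving 14 mild, 13 severe and 6 normal arrays. Replicate numbers follow the order of the samples and pair nothing. The labels used here give no scan date, slide or batch, so no batch could be tested. Of 528 pairs of arrays none held identical values. Correlations over the 13680 genes tested ranged from 0.839 to 0.990, so each array counted as 1 sample.

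Probe sets were named from the platform annotation, with symbols updated through RefSeq's gene table of the human assembly GRCh38.p14, used for names and chromosomes only. Of 54675 probe sets, 41097 carried 1 gene, 1801 several and 11777 none. Of the 41097, 41043 matched the RefSeq table and 54 kept the symbol of the annotation. Only probe sets with 1 gene were used, and 62 control probe sets and 59 probe sets of Y-linked genes, XIST and TSIX were left out. Probe sets entered if their log2 value was above 3 in at least 6 arrays, the size of the smallest group. A gene was represented by its probe set with the highest mean over the 33 arrays, which left 13680 genes, 7014 of them with several probe sets. Among the genes the naming rule allowed, 1 called gene in the comparison of severe with mild lesions had another probe set that moved the opposite way at an unadjusted p under 0.05, and none in the other comparisons. DEFB4A had no probe set of its own and IL10 fell below the filter, so neither is analysed here.

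Tests were run in R 4.3.3 with limma 3.58.1 and the data.table package (1.17.8). A linear model with 3 group means was fitted to all 33 arrays at once (lmFit and eBayes), so that the groups share 1 estimate of spread per gene, and the 3 comparisons were read from it. P-values were adjusted by the Benjamini-Hochberg method over the 13680 genes of a comparison, and a gene was called at an adjusted p under 0.05. Counts at a fold of at least 2 are given beside. Fold changes carry the moderated standard error (SE) and group levels the standard deviation (SD). The number of arrays in a direction counts the arrays of the first group on the called side of the second group's mean.

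Gene lists, 31 in number, were fixed before the data were examined, from general knowledge of skin, psoriasis and the cells a biopsy can hold. They were written with the title of the series known, and that title names IL-17 genes and immune regulation, so their choice was not blind to the study's conclusion. Each list was tested with camera at a preset correlation of 0.01, adjusted over 93 tests, with camera at an estimated correlation and fry beside it. Fry asks whether the members of a list change at all, and camera whether they change more than other genes. A list counts as called by camera at the preset correlation. Fry is given for the comparison of the grades and, against normal skin, for the regulatory ligands and cytokines only. Against normal skin, where most genes were called, fry also called lists that camera did not. The Th2, cytotoxic and neutrophil lists were among them, higher in both grades. With an estimated correlation the calls that held were the IL-17 response and the stress keratins, in each comparison with normal skin, 4 of 32. Counts of called members are over all genes, and "adjusted over the list alone" means that only the members were adjusted. A list score is the mean over members of the values centred over all arrays.

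The genes named were limited by a rule fixed before the data were examined. For each comparison these are the 8 largest rises and 8 largest falls among genes called at 2-fold or more, a fixed set of cytokine, T-cell and keratinocyte genes whether called or not, and up to 4 called members of each list with the largest change, or 2 members where none was called. Genes whose level mostly reflects a common inherited variant were left out, as were Y-linked genes, XIST and TSIX. Other X-linked genes stayed in. The rule allowed 208 genes, of which 125 were kept for the text after their values had been seen. Of the genes dropped, 7 left the text last, when reversed results, lost calls and distant arrays were already known.

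RNA quality was measured as the mean 3' minus 5' log2 difference of the 2 control transcripts ACTB and GAPDH, compared by two-sided permutation tests, exact for comparisons with normal skin and with 100000 resamples between the lesional groups. Correlations over arrays used 100000 permutations, whose smallest possible p is 1e-05. The overlap of the 2 comparisons with normal skin was set beside 100 simulations of unchanged groups sharing the normal arrays.

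The gene calls and the share measure for RNA quality were tested on simulated data with 200 of 13680 genes changed by known amounts. The list calls were tested with 1 shifted list among 30 unshifted ones. The correlations, the search for distant arrays and the comparison of epidermal with immune genes were not tested so. Noise was drawn for each gene on its own, so simulated lists lacked the correlation between members that real lists have. Recovery of the shifted list therefore says little about the list calls here. The changed genes and all list members were drawn from genes with a mean log2 value above 5. Recovery of genes nearer the floor, where several cytokines lie, was therefore not measured. The 200 changed genes are also a far smaller share than the genes called in the data. The share measure was simulated only at a log2 of 2, where a share of 0.5 came back as 0.499. Genes called between the grades had a median change of 0.477. In the simulated comparison of mild with normal arrays 45.8%, 77.6% and 95.9% of genes changed by a log2 of 0.5, 1 and 2 were called, with 4.46% false among the calls. For severe against normal these were 33.3%, 84.5% and 96.9% with 4.2% false, and for severe against mild 47.5%, 94.4% and 98.6% with 7.34% false. Alternatives covered the filter, the normalization, the choice of probe set, the arrays in the fit, the variance model, array weights, covariates for RNA quality and for sebaceous, T-cell and fat content, a rank test, the threshold, each normal array left out and the correlation of the gene lists. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.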

Results

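Gene expression was measured in 33 human skin biopsies on Affymetrix expression arrays, 1 array per biopsy. The arrays fell into 3 groups by the disease state in the labels, with 14 biopsies of mild plaque psoriasis, 13 of severe plaque psoriasis and 6 of normal skin. Plaque psoriasis is a chronic inflammatory skin disease in which the epidermis thickens and fills with immune cells. All lesional and normal biopsies were labelled as taken before treatment. The labels of the 6 normal arrays disagreed with each other, giving normal skin as the disease state and non-lesional biopsy as the source, so whether these samples came from people without psoriasis stays open, and normal skin is used here as the name of the group. Each sample carried its own donor label, so p-values measured the spread between donors. Of the 54675 probe sets, between 58.9% and 60.1% lay above a log2 value of 3 on each array, and the median log2 value per array ranged from 5.07 to 5.29. The number of arrays, above all the 6 of normal skin, limited the precision.

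Lesions and normal skin separated fully on the first principal component of the 13680 tested genes, which held 40.4% of the variance. Normal arrays scored between 82.9 and 122 on it, mild lesions between -54.7 and -11.1 and severe lesions between -28.1 and 14.5. The second component held 10.4% of the variance, with all severe lesions between -39.9 and -9.43 and mild lesions between -7.35 and 57.4. Normal arrays lay between 1.86 and 49.8 on it, within the mild range. Severe lesions thus stood apart from mild lesions and normal skin alike, and this component does not order the groups by grade.

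**Figure D1:**
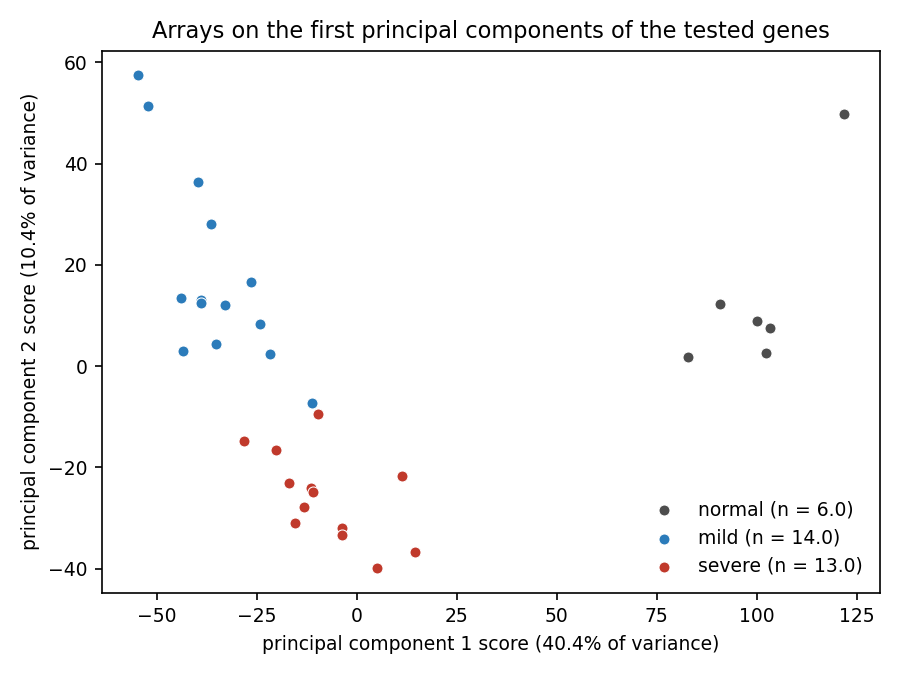
Each point is 1 array, placed by its scores on the first (x axis) and second (y axis) principal component of the tested genes and coloured by group. Normal skin lies apart on the first component, at 82.9 or above. On the second, the ranges of the mild (-7.35 to 57.4) and severe (-39.9 to -9.43) lesions do not overlap, and normal skin (1.86 to 49.8) lies within the mild range.

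The comparison of mild lesions (n = 14) with normal skin (n = 6) asked which genes the mild grade of the disease changes. SERPINB4, a serine protease inhibitor of squamous epithelium, lay at or below a log2 value of 3 on all 6 normal arrays and averaged 13.48 ± 0.33 (SD, n = 14) in mild lesions, at least 1433-fold higher (adjusted p = 7.2e-33, limma). On the same bound, TMPRSS11D, an airway-type serine protease, was at least 461-fold higher, the calcium-binding alarmin S100A12 at least 366-fold and SPRR2C at least 320-fold. CXCL8, the chemokine that draws neutrophils, was at least 291-fold higher (adjusted p = 7.91e-15, the largest of these 4). S100A7A rose by 11.25 ± 0.24 (log2, SE), TCN1, a vitamin B12-binding protein, by 10.05 ± 0.30, and S100A9, a subunit of calprotectin, by 8.47 ± 0.26. S100A7A was above a log2 value of 3 on 2 of the 6 normal arrays and TCN1 on 3.

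The largest fall in mild lesions was that of WIF1, a secreted Wnt inhibitor, which changed by -7.30 ± 0.72 (log2, SE) and was above a log2 value of 3 on 4 of 14 mild arrays. BTC, an epidermal growth factor receptor ligand, changed by -6.13 ± 0.45, with 1 mild array above that value, and IL37, an anti-inflammatory member of the interleukin-1 family, by -5.28 ± 0.82 (adjusted p = 1.75e-06). RAB3B, which regulates vesicle release, was at least 31.0-fold lower and WDR72 at least 30.5-fold lower, since no mild array exceeded a log2 value of 3. ANKRD33B (-5.54 ± 0.31), TPPP (-5.53 ± 0.46) and FGFBP2 (-5.39 ± 0.63) completed the 8 largest falls. Every one of these 16 genes lay on its side of the normal mean in 14 of 14 mild arrays.

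In all, limma called 8711 of 13680 genes (63.7%) at an adjusted p under 0.05, of which 5107 were higher and 3604 lower in mild lesions. At least 2-fold changes numbered 1883 higher and 1434 lower. Centring each array on its median, which shifted the median of all genes by -0.137 (log2), left 4124 higher and 4575 lower, so the share of higher calls moved from 58.6% to 47.4%. Changes of either direction are therefore given against normalized values and not as a shift of the whole transcriptome.

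Genes that keratinocytes switch on in response to interleukin-17 rose nearly without exception. Of the 21 measured members of that list, 20 were higher and 1 did not pass, the same counts when adjusted over the list alone, with a median of 5.81 (5.30 with genes at the floor held at their bound). LCN2, an iron-binding antimicrobial protein, rose by 6.08 ± 0.41 (log2, SE) and CCL20, the ligand of CCR6 on Th17 cells, by 5.81 ± 0.51. S100A7, already at 12.14 in normal skin, rose by 2.57 ± 0.25, which may be understated since lesions lay near the upper limit of the signal. The list was higher in 14 of 14 arrays (camera adjusted p = 1.02e-15) and stayed called with an adjusted p = 0.0392 with an estimated correlation. Among the IL-23 and IL-17 cytokines and receptors, 9 of 13 were higher, and 10 when adjusted over the list alone. IL17A itself was at least 5.86-fold higher (adjusted p = 1.1e-07), IL17F at least 1.77-fold (0.00105), IL26 at least 27.0-fold (6.18e-16) and IL12B, a subunit of IL-12 and IL-23, at least 6.98-fold (5.97e-05). IL23A rose by 1.42 ± 0.33 and IL1B by 5.32 ± 0.67. IL22 differed by 1.76 ± 0.92 and did not pass (adjusted p = 0.0933), being above a log2 value of 3 on 7 of 14 mild arrays. It was called with only the 2 groups in the fit (adjusted p = 0.0414) and with a rank test (0.00683). The cytokine list was called (median 1.69, 14 of 14 arrays, camera adjusted p = 0.0137), with an adjusted p = 0.665 with an estimated correlation.

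Interferon-responsive genes rose together. All 22 members of the type I interferon response were higher (median 3.40), with the antiviral genes OASL at 7.62 ± 0.38 (log2, SE) and RSAD2 at 7.17 ± 0.52 above normal skin. All 13 measured members of the interferon-gamma and Th1 list were higher (median 2.5), among them the T-cell chemokines CXCL10 (6.38 ± 0.48) and CXCL9 (6.30 ± 0.54), and IFNG was at least 1.13-fold higher (adjusted p = 0.00567). The 2 lists gave the same counts when adjusted over the list alone and were higher in 14 of 14 arrays. Their camera adjusted p-values were 3.32e-14 and 1.1e-05, and each had an adjusted p = 0.387 with an estimated correlation. The Th2 list was not called (camera adjusted p = 0.503), with 5 of 9 members higher, such as IL4R (2.94 ± 0.22), and 1 lower, the transcription factor GATA3 (-1.66 ± 0.17).

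T-cell transcripts and the receptors that regulate T cells rose as well. Of 17 measured T cell genes, 16 were higher and none lower, with CD28 up by 3.83 ± 0.42 (log2, SE), CD2 by 3.56 ± 0.37 and CD3D by 2.62 ± 0.30. Of the 13 measured checkpoint and regulatory T cell genes, 11 were higher and 1 lower. CTLA4, which restrains T-cell activation, rose by 6.57 ± 0.34 and was above a log2 value of 3 on 1 of 6 normal arrays, ICOS was at least 14.8-fold higher, TNFRSF4 rose by 2.92 ± 0.32, IL2RA by 2.55 ± 0.36, CD69 by 1.42 ± 0.29 and FOXP3, the transcription factor of regulatory T cells, by 1.24 ± 0.21. Adjustment over the list alone left these counts as they were. The T cell list had a median of 2.19 and a camera adjusted p = 0.000105, with an adjusted p = 0.706 with an estimated correlation. The checkpoint list had a median of 1.42 (1.15 with genes at their bound) and a camera adjusted p = 0.00849, with an adjusted p = 0.681 with an estimated correlation. Both were higher in 14 of 14 arrays. Regulatory ligands and cytokines moved both ways, 7 of 14 higher and 2 lower, and the list was not called (camera adjusted p = 0.142). Fry, which asks only whether members change at all, called it higher (adjusted p = 2.35e-08). CD274, the ligand PD-L1, rose by 5.96 ± 0.31, SOCS3 by 2.32 ± 0.29, and the tryptophan-degrading enzyme IDO1 was at least 7.54-fold higher, whereas IL37 fell. IL10 stayed below the filter on low values and was not tested.

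Other immune cell lists differed less uniformly. Of 12 cytotoxic and NK cell genes 9 were higher and 1 lower (not called, camera adjusted p = 0.0618), with GZMB, a protease of cytotoxic granules, up by 7.21 ± 0.51 and the adhesion molecule NCAM1 changed by -3.14 ± 0.34 (log2, SE). GZMB was above a log2 value of 3 on 1 of 6 normal arrays. Of 14 dendritic cell genes 10 were higher and 1 lower, led by CD80 (at least 5.54-fold), CCR7 (2.63 ± 0.37) and LAMP3 (2.54 ± 0.18). That list passed in 13 of 14 arrays with a median of 1.28 (camera adjusted p = 0.0445), with an adjusted p = 0.714 with an estimated correlation. It was not called without normal replicate 1 (adjusted p = 0.0681) or 4 (0.0603), while the cytotoxic list was called without normal replicate 6 (0.0438). Of 6 neutrophil genes 5 were higher, such as the chemokine receptor CXCR2 (2.84 ± 0.26), and 1, AQP9 (-3.72 ± 0.52), was lower (camera adjusted p = 0.35). Langerhans cell genes had 4 of 6 members lower and 1 higher (camera adjusted p = 0.236), with CD207, the langerin of these cells, at -2.26 ± 0.63. The macrophage and monocyte list (1 of 11 higher, 2 lower), the mast cell list (1 of 8 higher, 4 lower), the B and plasma cell list (2 of 5 higher, 1 lower) and the MHC class II list (1 of 9 higher, none lower) were not called, with camera adjusted p-values of 0.559, 0.142, 0.929 and 0.827. For B and plasma cells, camera pointed down while the median (0.53) and mean (0.74) were above 0. For MHC class II the median was -0.03 and the mean 0.07. Adjusted over the list alone, cytotoxic cells had 10 genes higher and 1 lower, and B and plasma cells 1 higher and 1 lower.

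Cell cycle, stress keratin and early cornified envelope genes rose, while most late differentiation genes fell. All 23 cell cycle genes were higher (median 1.99), including MKI67 (4.89 ± 0.43) and KIF20A (3.93 ± 0.49), and all 15 measured stress keratin and early cornified envelope genes were higher (median 4.63), including KRT16 (4.67 ± 0.30), the only keratin of the list analysed here, RHCG (6.52 ± 0.45) and KLK6 (6.08 ± 0.60). Both held for every member when adjusted over the list alone and in 14 of 14 arrays. The cell cycle list had a camera adjusted p = 9.76e-10, with an adjusted p = 0.558 with an estimated correlation, and the stress keratin list a camera adjusted p = 1.89e-13, with an adjusted p = 0.0392 with an estimated correlation. Of 13 late differentiation genes, 10 were lower and 3 did not pass. KRT77 changed by -3.07 ± 0.31 (log2, SE), the tight junction protein CLDN23 by -2.56 ± 0.24 and LORICRIN, the main protein of the cornified envelope, by -2.13 ± 0.71 (adjusted p = 0.0101). That list was lower in 14 of 14 arrays (median -1.27, camera adjusted p = 0.00138), with an adjusted p = 0.567 with an estimated correlation.

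The sebaceous gland, fibroblast and adipocyte lists were called lower in mild lesions. All 14 measured sebaceous gland genes were lower, among them ELOVL3 (-5.09 ± 0.87, log2, SE) and THRSP (-5.03 ± 0.98), in 14 of 14 arrays (median -2.85, camera adjusted p = 0.00015), with an adjusted p = 0.681 with an estimated correlation. The normal arrays were uneven in this score, from -0.68 to 4.17, and overlapped the mild arrays (-1.65 to 0.58). Of 17 fibroblast and matrix genes 12 were lower and 1 higher, with ELN at -2.63 ± 0.60 and FN1 at -1.52 ± 0.27 (list median -0.47, 14 of 14 arrays, camera adjusted p = 0.00504), with an adjusted p = 0.714 with an estimated correlation. Of 12 adipocyte genes 5 were lower, and 3 when adjusted over the list alone, with CFD at -2.52 ± 0.32 (list median -1.41, 12 of 14 arrays, camera adjusted p = 0.0484), with an adjusted p = 0.714 with an estimated correlation. The adipocyte call was lost without normal replicate 1 (median -0.88, adjusted p = 0.0924), 3 (-1.14, 0.0948), 4 (-1.34, 0.0564) or 5 (-1.31, 0.0746), and the sweat gland list was called without normal replicate 6 (-3.96, 0.00384). With RNA quality as a covariate the adipocyte list was not called (adjusted p = 0.0535), and the sweat gland list was called lower (median -3.30, 0.033). Lists not called were sweat gland (5 of 9 lower, 6 adjusted over the list alone, camera adjusted p = 0.0543), melanocyte (2 of 7 lower, 0.155), muscle (3 of 7 lower, 0.101) and Schwann cell and nerve (2 of 3 lower, 0.0759). Blood was represented by HBB alone, which changed by -4.51 ± 0.91. Hair follicle (2 higher and 2 lower of 10, camera adjusted p = 0.777), endothelium and adhesion (3 higher and 4 lower of 16, 0.561), fatty acid and sterol synthesis (5 higher and 1 lower of 13, 0.392) and immediate-early and handling genes (5 higher and 3 lower of 12, 0.782) moved both ways. Camera pointed down for hair follicle, whose median was 0.66, and for endothelium, whose median was -0.14 and mean 0.05. The immediate-early median of 0.06 turned to -0.08 with each array centred on its median. With the sebaceous gland score as a covariate, 10 of the 85 named genes called in this comparison no longer passed, namely IFNG, CD69, LORICRIN, CCL18, CD207, CD79B, ELOVL3, THRSP, OCA2 and SELE. ELOVL3 (-0.88) and THRSP (-1.27) are members of that list, so the covariate takes up most of their change by construction. The others kept part of theirs: IFNG 0.78, CD69 0.83, LORICRIN -0.91, CCL18 2.25, CD207 -1.09, CD79B -0.57, OCA2 -1.04 and SELE 1.29. GAL, a neuropeptide and likewise a member of the sebaceous gland list, was lower by 4.72 ± 1.13 without the covariate and turned to 1.12.

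The comparison of severe lesions (n = 13) with normal skin (n = 6) asked the same of the severe grade. The same kinds of gene led the rises. S100A7A rose by 11.15 ± 0.24 (log2, SE), SERPINB4 was at least 1115-fold higher (adjusted p = 2.91e-32), TCN1 rose by 9.42 ± 0.31, and S100A12 was at least 274-fold higher. TMPRSS11D was at least 248-fold and SPRR2C at least 219-fold higher. S100A9 rose by 8.20 ± 0.26. ATP12A, a proton and potassium pump, rose by 7.72 ± 0.43. The largest falls were of WIF1 (-6.07 ± 0.72), NPTX1 (-5.32 ± 0.38), BTC (-5.11 ± 0.46), PM20D1 (-5.06 ± 1.35), RAB3B (-4.92 ± 0.33), CADPS (-4.64 ± 0.49), ANKRD33B (-4.59 ± 0.32) and GAL (-4.50 ± 1.14). Of these 16 genes, PM20D1 and GAL lay below the normal mean in 12 of 13 severe arrays and the other 14 on their side in 13 of 13. With the sebaceous gland score as a covariate PM20D1 turned to 0.25 and GAL, itself a member of that list, to 0.11.

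In severe lesions limma called 7513 genes (54.9%), 4256 higher and 3257 lower, with 1501 higher and 993 lower by at least 2-fold. Centring each array on its median, which shifted the median of all genes by -0.103, gave 3594 higher and 4145 lower, a share of higher calls of 46.4% against 56.6%. The difference between the 3' and 5' control probe sets of ACTB and GAPDH, a measure that grows as RNA degrades, averaged 1.33 ± 0.25 (log2, SD) in severe lesions and 1.94 ± 0.24 in normal skin (exact permutation p = 0.000147, two-sided). It averaged 1.89 ± 0.46 in mild lesions, which was not distinguishable from normal skin (exact permutation p = 0.787).

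The IL-17 response of keratinocytes again had 20 of 21 members higher (median 5.00, 4.83 with genes at their bound). CCL20 rose by 6.10 ± 0.52 (log2, SE), LCN2 by 6.03 ± 0.42 and S100A7 by 2.51 ± 0.25, again near the upper limit of the signal. The list was higher in 13 of 13 arrays (camera adjusted p = 4.42e-17) and had an adjusted p = 0.0392 with an estimated correlation. Of the 13 IL-23 and IL-17 cytokines and receptors 7 were higher and none lower. IL26 was at least 17.4-fold (adjusted p = 2.17e-14), IL12B at least 3.98-fold (0.00167) and IL17A at least 1.64-fold higher (0.005), IL17A being higher in 12 of 13 arrays. IL23A rose by 1.13 ± 0.34 (12 of 13 arrays, adjusted p = 0.00525) and had an adjusted p = 0.0544 with RNA quality as a covariate. IL17F (0.67 ± 0.44, adjusted p = 0.194), IL22 (1.68 ± 0.93, 0.125) and IFNG (0.62 ± 0.34, 0.119) did not pass, though a rank test called IL22 (0.0169) and IFNG (0.00597). The cytokine list had a median of 1.49 in 13 of 13 arrays (camera adjusted p = 0.0468), with an adjusted p = 0.706 with an estimated correlation. Its median was 0.77 with genes at their bound, and with RNA quality as a covariate the list was no longer called (median 1.22, adjusted p = 0.0758), nor without normal replicate 1 (1.36, 0.0898) or 4 (1.25, 0.082), nor with the probe set of largest SD (0.198). With the sebaceous gland score as a covariate IL17A (1.10, adjusted p = 0.107) and IL23A (0.96, 0.0694) were no longer called.

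Interferon and T-cell lists were raised in severe lesions too. All 22 type I interferon genes were higher (median 2.96), with OASL at 7.33 ± 0.38 (log2, SE), and 11 of 13 interferon-gamma and Th1 genes (median 1.72), with CXCL9 at 6.44 ± 0.54 and CXCL10 at 6.35 ± 0.49. Their camera adjusted p-values were 5.93e-15 and 2.93e-05, with an adjusted p = 0.387 and an adjusted p = 0.428 with an estimated correlation. Of 17 T cell genes 12 were higher (13 adjusted over the list alone), with CD28 at 3.20 ± 0.42, CD2 at 2.74 ± 0.37 and CD3D at 2.07 ± 0.30. Of 13 checkpoint and regulatory T cell genes 9 were higher and 1 lower (10 and 1 adjusted over the list alone), with CTLA4 at 5.97 ± 0.34, ICOS at least 7.50-fold higher and FOXP3 at 0.86 ± 0.21. The medians of the 2 lists were 1.57 and 0.86, with camera adjusted p-values of 0.00138 and 0.0115, and an adjusted p = 0.714 and an adjusted p = 0.681 with an estimated correlation. All 4 lists were higher in 13 of 13 arrays. CD69 rose by 0.73 ± 0.30 in 11 of 13 arrays (adjusted p = 0.0374), a call that was lost without normal replicate 3 (0.72, adjusted p = 0.0583), without normal replicate 5 (0.65, 0.0888) and without normal replicate 6 (0.64, 0.0937). It was also lost with RNA quality (0.53, 0.223), the sebaceous gland score (0.26, 0.572) or the adipocyte score (0.70, 0.0598) as a covariate, a rank test (0.0838), centred arrays (0.07), only the 2 groups (0.0629), no filter (0.0566) and without the array of each group that stands apart (0.0747). Regulatory ligands were not called as a list (camera adjusted p = 0.334), with 7 of 14 higher, such as CD274 (5.30 ± 0.32), and 2 lower, such as IL37 (-3.76 ± 0.83). Fry called that list higher (adjusted p = 4.29e-05).

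Among the other lists in severe lesions, 9 of 14 dendritic cell genes were higher and 1 lower, with ITGAX at 2.33 ± 0.29 and LAMP3 at 2.18 ± 0.18 (list median 1.02, 13 of 13 arrays, camera adjusted p = 0.0471), with an adjusted p = 0.714 with an estimated correlation and an adjusted p = 0.0707 with RNA quality as a covariate. The call was lost without normal replicate 1 (adjusted p = 0.0824), 3 (0.0504) or 4 (0.0671). Of 23 cell cycle genes 20 were higher and 3 did not pass, with MKI67 at 4.55 ± 0.43 (list median 1.57, 13 of 13 arrays, camera adjusted p = 4.32e-09), with an adjusted p = 0.558 with an estimated correlation. All 15 stress keratin genes were higher, with KRT16 at 4.42 ± 0.30 (list median 4.31, 13 of 13 arrays, camera adjusted p = 9.43e-16), with an adjusted p = 0.0392 with an estimated correlation. The sebaceous gland list was the only one called lower, with 10 of 14 members below normal skin in 12 of 13 arrays (median -2.08, camera adjusted p = 0.001), with an adjusted p = 0.706 with an estimated correlation. Its scores in severe lesions (-1.09 to 2.84) overlapped those of normal skin (-0.68 to 4.17). Late differentiation was mixed, 2 of 13 higher and 2 lower (camera adjusted p = 0.142), with KRT77 at -2.46 ± 0.31 and CLDN23 at -2.36 ± 0.24 lower, CASP14, a protease of the cornifying layer, 1.49 ± 0.36 higher, and LORICRIN at -0.89 ± 0.72 not passing (adjusted p = 0.304), though it was called with only the 2 groups in the fit (0.00736) and with a rank test (0.0127). No sweat gland or melanocyte gene passed, though MITF was called lower with each array centred (-0.60, adjusted p = 0.0358), with only the 2 groups (0.00684) and with a rank test (0.019). Without normal replicate 6 the sweat gland median went from -0.56 to -1.95, also not called (adjusted p = 0.106). Of 12 adipocyte genes PLIN1, the coat protein of fat droplets, was higher by 3.02 ± 1.13 in 13 of 13 arrays (adjusted p = 0.0244) and CFD lower by 1.15 ± 0.32, a PLIN1 call that RNA quality as a covariate (adjusted p = 0.13) and a rank test (0.117) did not keep and that was lost without normal replicate 2 (2.17, adjusted p = 0.112) and without normal replicate 6 (2.02, 0.131). Not called either were the Th2 (4 of 9 higher, 1 lower, camera adjusted p = 0.53), cytotoxic and NK cell (4 of 12 higher, 1 lower, 0.101), Langerhans cell (1 of 6 higher, 4 lower, 0.215), neutrophil (3 of 6 higher, 1 lower, 0.385), mast cell (1 of 8 higher, 4 lower, 0.234), B and plasma cell (1 of 5 lower, 0.982) and fibroblast lists (3 of 17 lower, 0.0759), the last being called lower with RNA quality as a covariate (median -0.45, adjusted p = 0.0134) and without normal replicate 1 (-0.36, 0.0394). For melanocytes and for macrophages camera pointed down, at medians of 0.25 and 0.16. The MHC class II median of 0.08 turned to -0.02 with each array centred on its median.

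**Figure D2:**
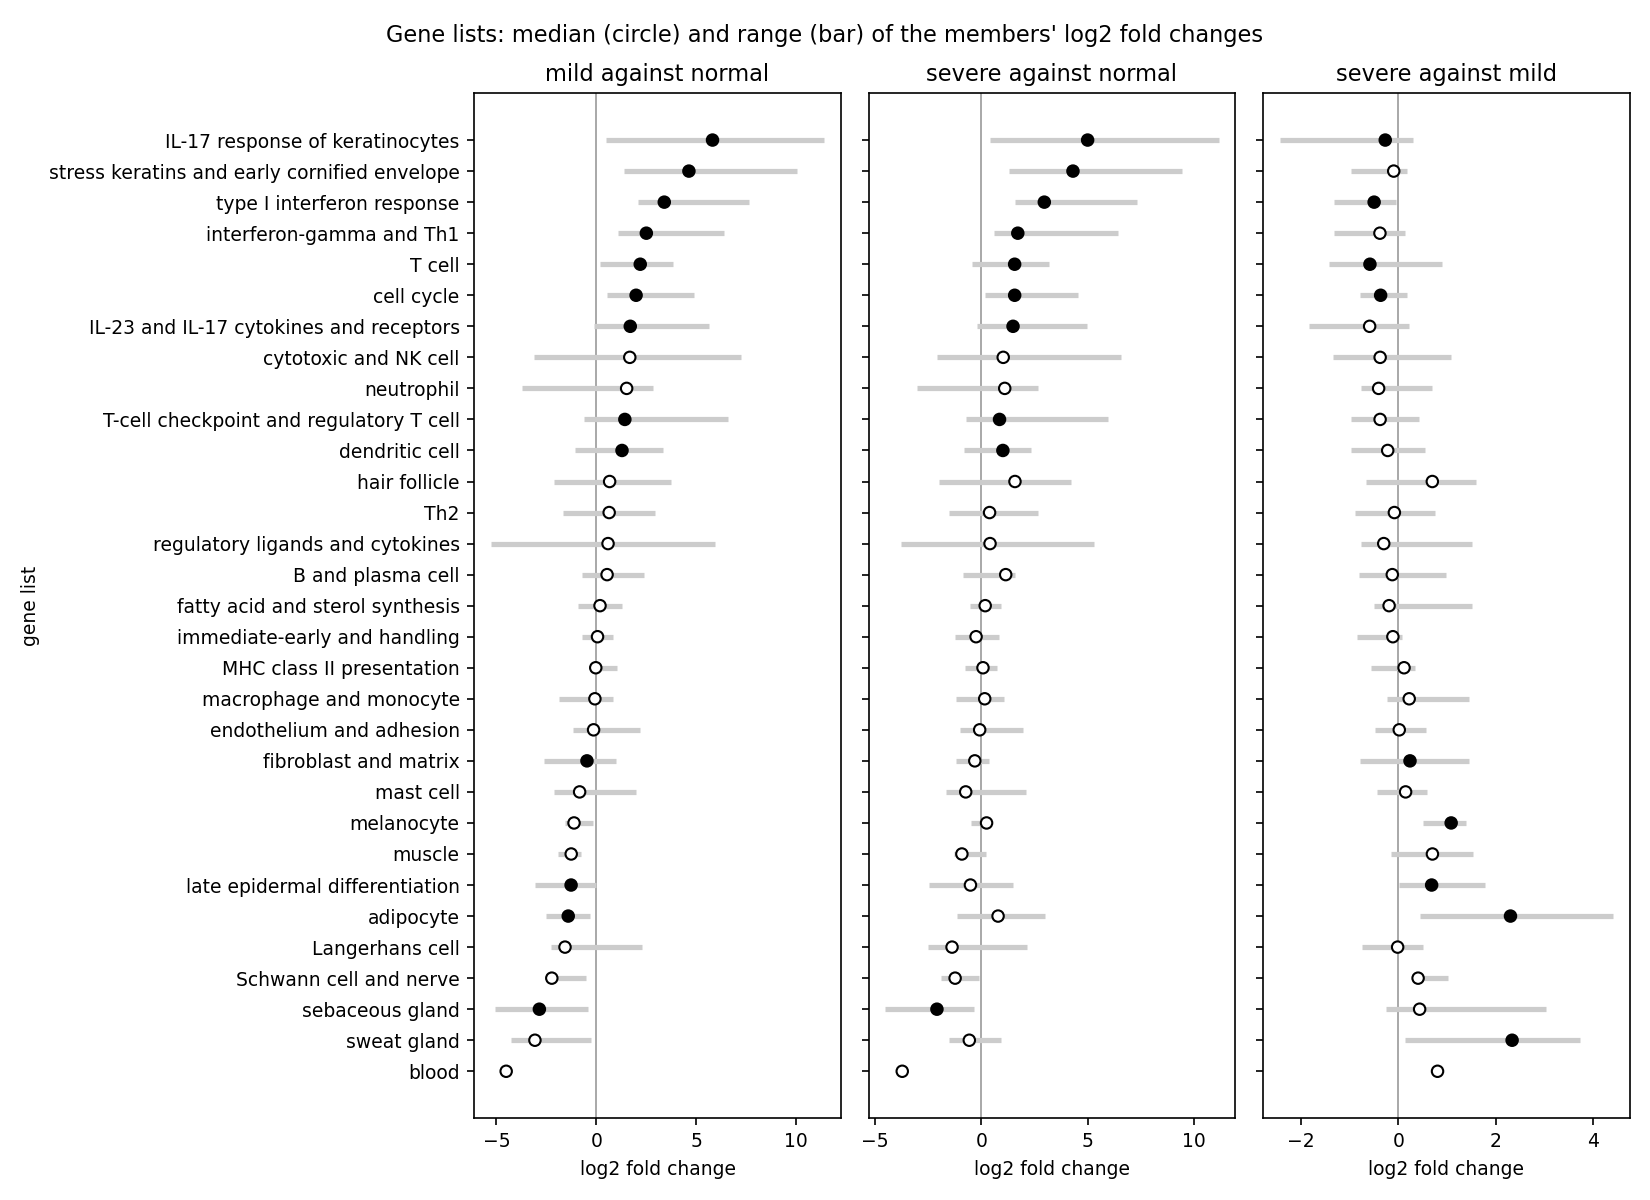
For each of the 31 gene lists (y axis), the circle gives the median and the bar the range of its members' log2 fold changes (x axis) in 1 comparison per panel, and a filled circle marks a camera adjusted p under 0.05. The IL-17 response lies at 5.81 and 5.00 in the comparisons with normal skin and at -0.27 between the grades, while the adipocyte list turns from -1.41 in mild lesions to a severe minus mild difference of 2.30.

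Mild and severe lesions were next set side by side to ask how far their changes are shared. In both grades 3743 genes were higher and 2572 lower than in normal skin, 6315 in all, and 22 genes were called in opposite directions. Independent lists of these sizes would share 1589 and 858 genes. Of the 6315, 2109 were at least 2-fold changed in both. The fold changes of all genes correlated across genes at r = 0.916 (covariance 1.04). Because both comparisons use the same 6 normal arrays, unchanged groups simulated against shared controls gave a median r of 0.708 and a covariance of 0.0449, a difference of covariances of 1.00. With the normal arrays split into sets of 3 and 3 (20 assignments), r was 0.824 (range 0.781 to 0.877) and the medians were 2656.5 genes higher and 1716 lower in both. Among the 6315 shared genes, the change was larger in mild lesions for 4199 (66.5%).

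The direct comparison of severe (n = 13) with mild (n = 14) lesions asked whether the grades share the activation of IL-17 genes and differ in genes that regulate immunity, the question the study's title names. The IL-17 response, type I interferon, T cell and cell cycle lists were called lower, and the adipocyte, sweat gland, late differentiation, melanocyte and fibroblast lists higher, in severe lesions. Most members of the lists called lower did not pass, and none of these calls remained with an estimated correlation. IL17A was lower by 1.83 ± 0.35 (log2, SE), 5.55 in mild against 3.72 in severe lesions, in 11 of 13 severe arrays (adjusted p = 0.000225), and IL17F by 1.02 ± 0.34 in 12 of 13 (0.0216). IL17A was above a log2 value of 3 on 14 of 14 mild and 8 of 13 severe arrays, and IL17F on 13 and 5. Of 21 genes of the keratinocyte response to IL-17, 7 were lower, while 3 examples that did not pass had differences of -0.06 ± 0.19 for S100A7, -0.05 ± 0.33 for LCN2 and 0.29 ± 0.40 for CCL20, and KRT16 did not pass either (-0.25 ± 0.24). S100A7 averaged 14.70 in mild and 14.64 in severe lesions, near the highest log2 value of the arrays (15.35 to 15.57), which leaves little room for a difference in it to show. The largest rises were of ADIPOQ, the adipocyte hormone adiponectin (4.41 ± 0.95, adjusted p = 0.000838), and PLIN1 (4.41 ± 0.89, 0.000412), each above the mild mean in 13 of 13 severe arrays.

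Limma called 4304 of 13680 genes (31.5%) between the grades, 1770 higher and 2534 lower in severe lesions, with 365 higher and 154 lower by at least 2-fold. Centring each array on its median gave 2018 higher and 2140 lower, a share of higher calls of 48.5% against 41.1%. The other large rises were of the sweat gland proteins PIP (3.73 ± 1.17, log2, SE, adjusted p = 0.0155), SCGB2A2 (3.47 ± 1.21, 0.0283) and SCGB1D2 (3.41 ± 1.04, 0.0131), of LGR5, a stem cell receptor of hair follicles (3.48 ± 0.64, 0.000162), CNKSR2 (3.43 ± 0.30, 1.22e-09) and TSPAN8 (3.38 ± 0.59, 8.89e-05), all in 13 of 13 arrays. The largest falls were of KRT24 (-2.54 ± 0.72, adjusted p = 0.00774), the interleukin-10 family cytokines IL19 (-2.44 ± 0.69, 0.0075) and IL24 (-2.30 ± 0.44, 0.000243), KLHDC7B (-2.24 ± 0.40), PAOX, a polyamine oxidase (-2.23 ± 0.32), the B-cell chemokine CXCL13 (-2.13 ± 0.46), CATSPERB (-2.13 ± 0.47) and TNIP3, an inhibitor of NF-kB signalling (-2.03 ± 0.50). Each of these falls lay below the mild mean in at least 11 of 13 severe arrays.

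**Figure D3:**
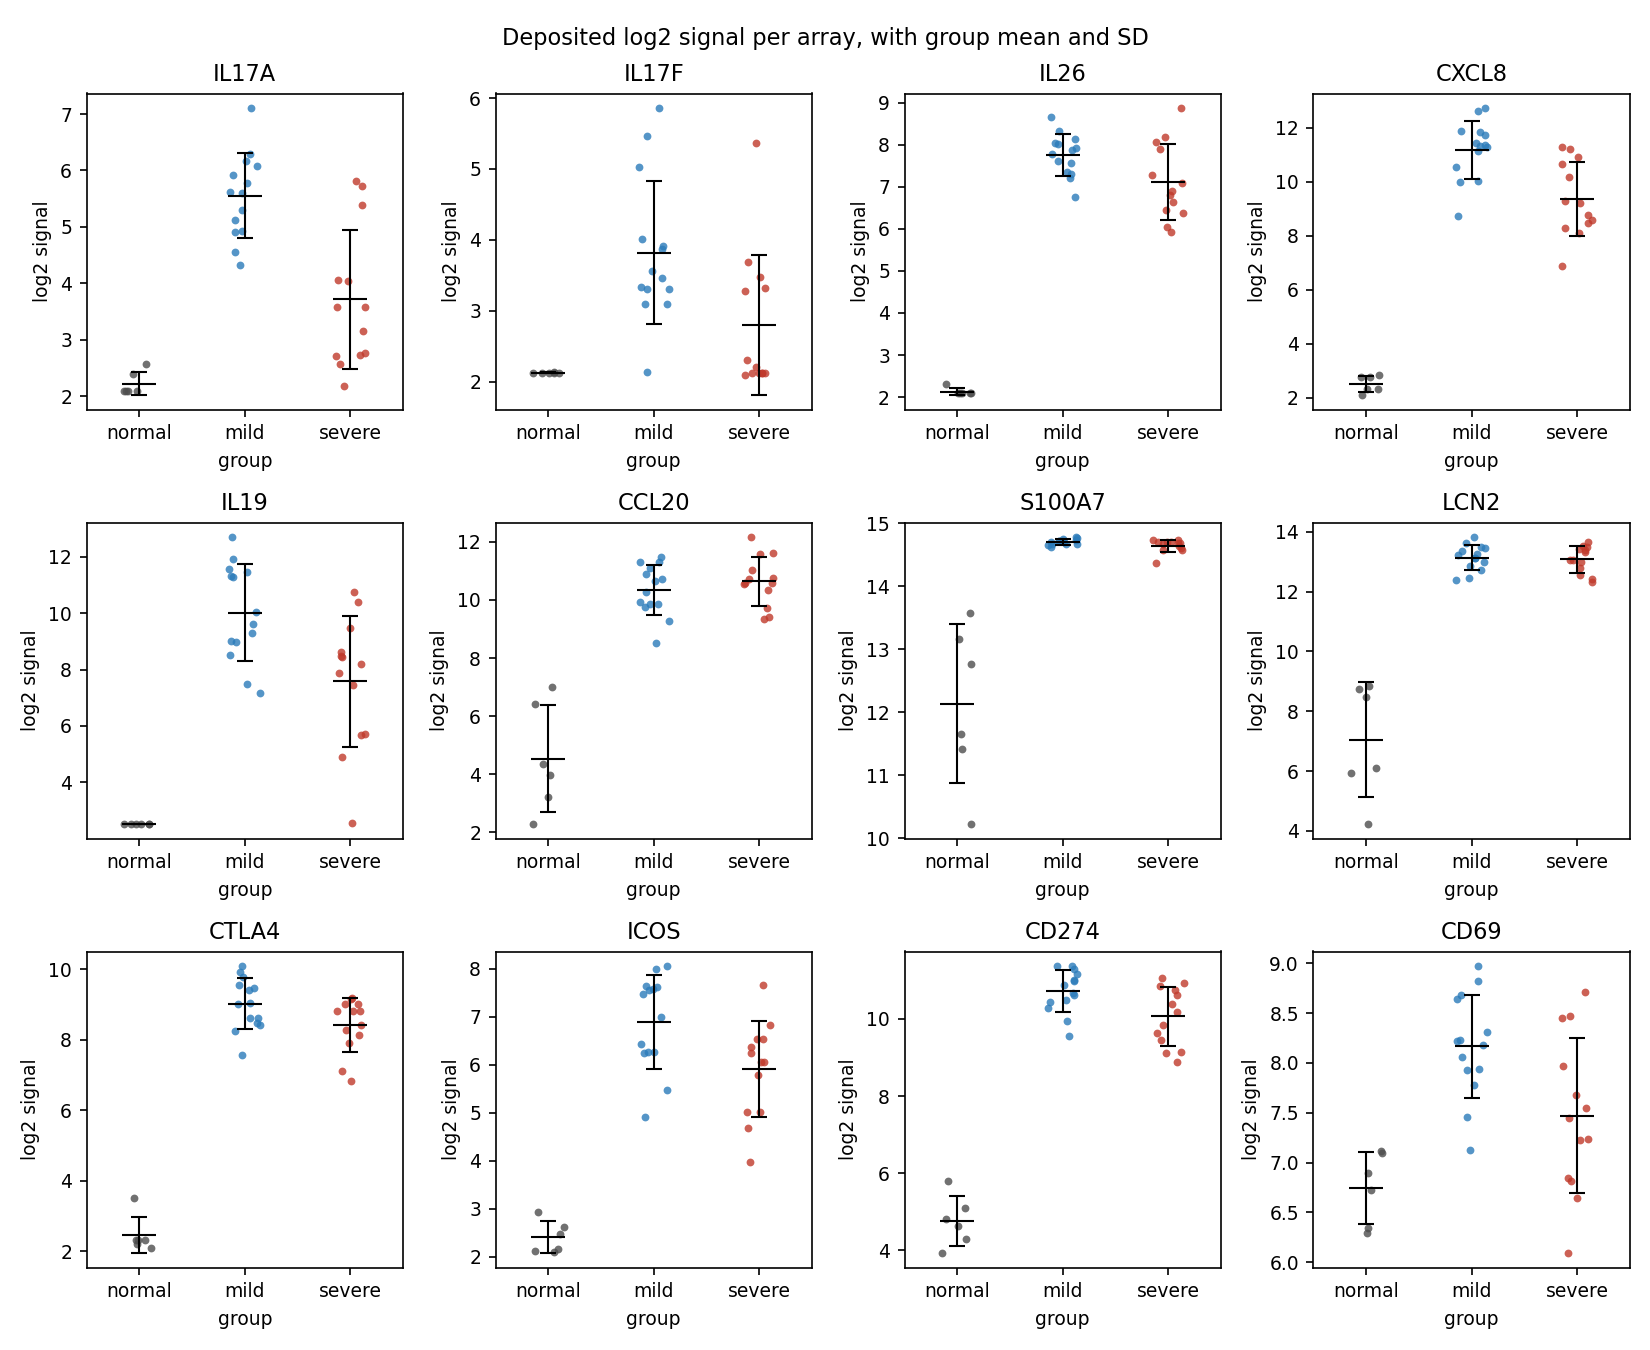
Each panel gives the deposited log2 signal (y axis) of 1 gene on every array by group (x axis), with the group mean and SD. IL17A averages 2.22 in normal skin, 5.55 in mild and 3.72 in severe lesions, while LCN2 averages 13.13 in mild and 13.08 in severe lesions.

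Of the 1770 genes higher in severe than in mild lesions, 1080 (61.0%) were lower in mild lesions than in normal skin, and of the 2534 genes lower in severe lesions, 1561 (61.6%) were higher in mild lesions than in normal skin. Independent lists would share 466.3 and 946. The mild arrays enter both comparisons, and over all genes the fold changes correlated at r = -0.542 (covariance -0.294) against -0.387 (-0.0190) for simulated unchanged groups, a difference of covariances of -0.275. With the mild arrays divided at random into sets of 7 for each comparison (20 divisions), the shares were 55.0% (range 44.7 to 61.6%) and 54.3% (44.8 to 61.1%).

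The called immune lists were lower in severe lesions by small amounts. Of 21 genes of the IL-17 response 7 were lower and 14 did not pass, and the 7 were mainly chemokines and cytokines such as IL19, CXCL1 (-1.92 ± 0.54, log2, SE) and CXCL8 (-1.81 ± 0.42). Its median was -0.27, in 11 of 13 arrays (camera adjusted p = 0.0492), with an adjusted p = 0.714 with an estimated correlation, and it was -0.53 with RNA quality as a covariate (adjusted p = 0.000214) and -0.38 with the adipocyte score (0.0949). That call was lost without normal replicate 1 (adjusted p = 0.0597), 3 (0.0508), 4 (0.0525) or 6 (0.0607), at the same median. Of 22 type I interferon genes 8 were lower, with IRF7 at -1.33 ± 0.24 and ISG15 at -1.06 ± 0.38 (list median -0.50, 10 of 13 arrays, camera adjusted p = 0.00821), with an adjusted p = 0.714 with an estimated correlation. With RNA quality as a covariate the interferon list (median -0.31, adjusted p = 0.0726) and ISG15 (-0.70, 0.334) were no longer called. Of 17 T cell genes 7 were lower and 1 higher (8 and 1 adjusted over the list alone), with the kinase LCK at -1.43 ± 0.29, CD6 at -1.30 ± 0.27 and CD3E at -1.09 ± 0.31, and CD3D at -0.55 ± 0.23 not passing (adjusted p = 0.0704). CD3D was called with array weights (-0.58, adjusted p = 0.0248) and with RNA quality as a covariate (-0.82, 0.0491). The T cell list had a median of -0.59 in 10 of 13 arrays (camera adjusted p = 0.0264), with an adjusted p = 0.714 with an estimated correlation. It was called with RNA quality as a covariate (median -0.82, adjusted p = 0.00322) and not with the adipocyte score (-0.50, 0.198). Of 23 cell cycle genes 7 were lower, with MCM2 at -0.80 ± 0.18 and MKI67 at -0.34 ± 0.34 not passing (list median -0.37, 10 of 13 arrays, camera adjusted p = 0.0149), with an adjusted p = 0.721 with an estimated correlation. Counts adjusted over the list alone were the same for the IL-17 response, interferon and cell cycle lists.

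Neither list of regulatory genes was called by camera between the grades, and most members did not pass. Fry, planned beside camera, called the regulatory ligands and cytokines lower (adjusted p = 0.0022) and did not call the checkpoint list (0.0803). Of 13 checkpoint and regulatory T cell genes 3 were lower, ICOS (-0.98 ± 0.34, log2, SE, 12 of 13 arrays, adjusted p = 0.0261), TIGIT (-0.86 ± 0.28, 10 of 13, 0.0194) and CD69 (-0.70 ± 0.23, 10 of 13, 0.0218), and 1 was higher, the transcription factor IKZF2 (0.42 ± 0.13, 11 of 13, 0.0105). CTLA4 (-0.60 ± 0.27, adjusted p = 0.0849) and FOXP3 (-0.38 ± 0.17, 0.0796) did not pass, though CTLA4 was called with RNA quality as a covariate (-0.95, adjusted p = 0.0413) and FOXP3 with quantile normalization (-0.44, 0.0345) or array weights (-0.42, 0.037). The list was not called (median -0.38, camera adjusted p = 0.296). Of 14 regulatory ligands and cytokines 5 were lower, including the cytokine signalling inhibitors SOCS1 (-0.77 ± 0.20) and SOCS3 (-0.74 ± 0.23), VSIR (-0.56 ± 0.13) and CD274 (-0.66 ± 0.25, 9 of 13 arrays, adjusted p = 0.0402), without a call for the list (camera adjusted p = 0.107). With the adipocyte score as a covariate SOCS1 (-0.58, adjusted p = 0.148) and SOCS3 (-0.28, 0.57) were no longer called. SOCS3 was not called with the probe set of largest SD (0.0905) or the T cell score (-0.58, 0.0797) either. IL26 was lower by 0.64 ± 0.25 in 9 of 13 arrays (adjusted p = 0.0456). Without the array of each group that correlated least with its group, ICOS (-0.85, adjusted p = 0.0662), CD69 (-0.61, 0.0546), CD274 (-0.54, 0.0901) and IL26 (-0.52, 0.111) no longer passed. IL26 and CD274 also lost the call with no filter on low values (adjusted p = 0.0719 and 0.064), with each array centred on its median (0.0654 and 0.0538), with array weights, with a rank test and with the sebaceous gland, T cell or adipocyte score as a covariate. ICOS and CD69 lost it with a rank test (0.0725 and 0.0661), CD69 with the sebaceous gland score (0.0532). IKZF2 lost it with the probe set of largest SD. With the T cell score as a covariate ICOS, TIGIT and CD69 moved to -0.32, -0.42 and -0.32 and were no longer called.

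Other immune lists gave no camera call between the grades, although single members differed. They were the IL-23 and IL-17 cytokines (4 of 13 lower, camera adjusted p = 0.101), interferon-gamma and Th1 (4 of 13 lower, 0.101, with IL12RB2 at -1.34 ± 0.23), Th2 (2 of 9 lower, 0.686, with IL4R at -0.89 ± 0.18), cytotoxic and NK cell (1 of 12 higher, 0.427), dendritic cell (5 of 14 lower, 0.41, with CCR7 at -0.94 ± 0.29), macrophage and monocyte (1 of 11 higher, 0.415, VSIG4 at 1.46 ± 0.46, which was not called with RNA quality as a covariate, at 1.23 and an adjusted p = 0.147, with the adipocyte score, at 0.73 and 0.442, or with a rank test), neutrophil (1 of 6 lower, 0.735) and mast cell (1 of 8 higher, 0.392). With RNA quality as a covariate the IL-23 and IL-17 cytokines (median -0.93, adjusted p = 0.0107) and the interferon-gamma and Th1 list (-0.68, 0.0137) were called lower, as they were with the probe set of largest SD (0.0335 and 0.046). Fry called the same 2 lists lower (adjusted p = 0.00719 and 0.0323) and none of the others listed here. In the Langerhans cell, B and plasma cell and MHC class II lists no gene passed. The Langerhans cell median of -0.02 turned to 0.02 with each array centred on its median, and for B and plasma cells the median was -0.13 and the mean 0.10. CXCL9 (0.14 ± 0.42), IL22 (-0.08 ± 0.72), IL23A (-0.29 ± 0.26) and IL12B (-0.81 ± 0.54) did not pass, nor did IFNG (-0.46 ± 0.26, adjusted p = 0.183), which passed with RNA quality as a covariate (-0.91, adjusted p = 0.0422).

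Late differentiation, adipocyte, sweat gland, melanocyte and fibroblast lists were called higher in severe than in mild lesions, though most melanocyte and fibroblast members did not pass. Of 13 late differentiation genes 7 were higher, and 11 when adjusted over the list alone, with CASP14 at 1.67 ± 0.28 (log2, SE), LCE2B at 1.07 ± 0.21 and FLG2 at 0.94 ± 0.32 (list median 0.68, 13 of 13 arrays, camera adjusted p = 5.84e-05), with an adjusted p = 0.387 with an estimated correlation. Of 12 adipocyte genes 11 were higher (median 2.30, 13 of 13 arrays, camera adjusted p = 2.28e-07), with an adjusted p = 0.387 with an estimated correlation. Of 9 sweat gland genes 5 were higher, and 7 adjusted over the list alone (median 2.34, 13 of 13 arrays, camera adjusted p = 0.006), with an adjusted p = 0.714 with an estimated correlation. With RNA quality as a covariate the sweat gland list fell to a median of 0.52 (adjusted p = 0.336) and was no longer called, while the adipocyte list stayed at 2.43 (6.15e-08). Of 7 melanocyte genes 2 were higher, OCA2 (1.39 ± 0.32) and MITF (0.77 ± 0.19; list median 1.08, 13 of 13 arrays, camera adjusted p = 0.0115), with an adjusted p = 0.706 with an estimated correlation. Of 17 fibroblast and matrix genes 5 were higher, such as FBLN1 (0.86 ± 0.16) and ELN (1.45 ± 0.47), and 1 lower, TNC (-0.78 ± 0.25; list median 0.24, 11 of 13 arrays, camera adjusted p = 0.0112), with an adjusted p = 0.714 with an estimated correlation and an adjusted p = 0.133 with RNA quality as a covariate. The mild arrays were uneven in these structures. For sweat glands 5 mild arrays scored at -3.42 or below and the other 9 at -0.33 or above, so that the group medians of the score differed by 0.94 and the means by 2.12. For melanocytes 2 mild arrays scored at -4.14 or below, and the medians differed by 0.30 against 1.06 for the means.

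**Figure D4:**
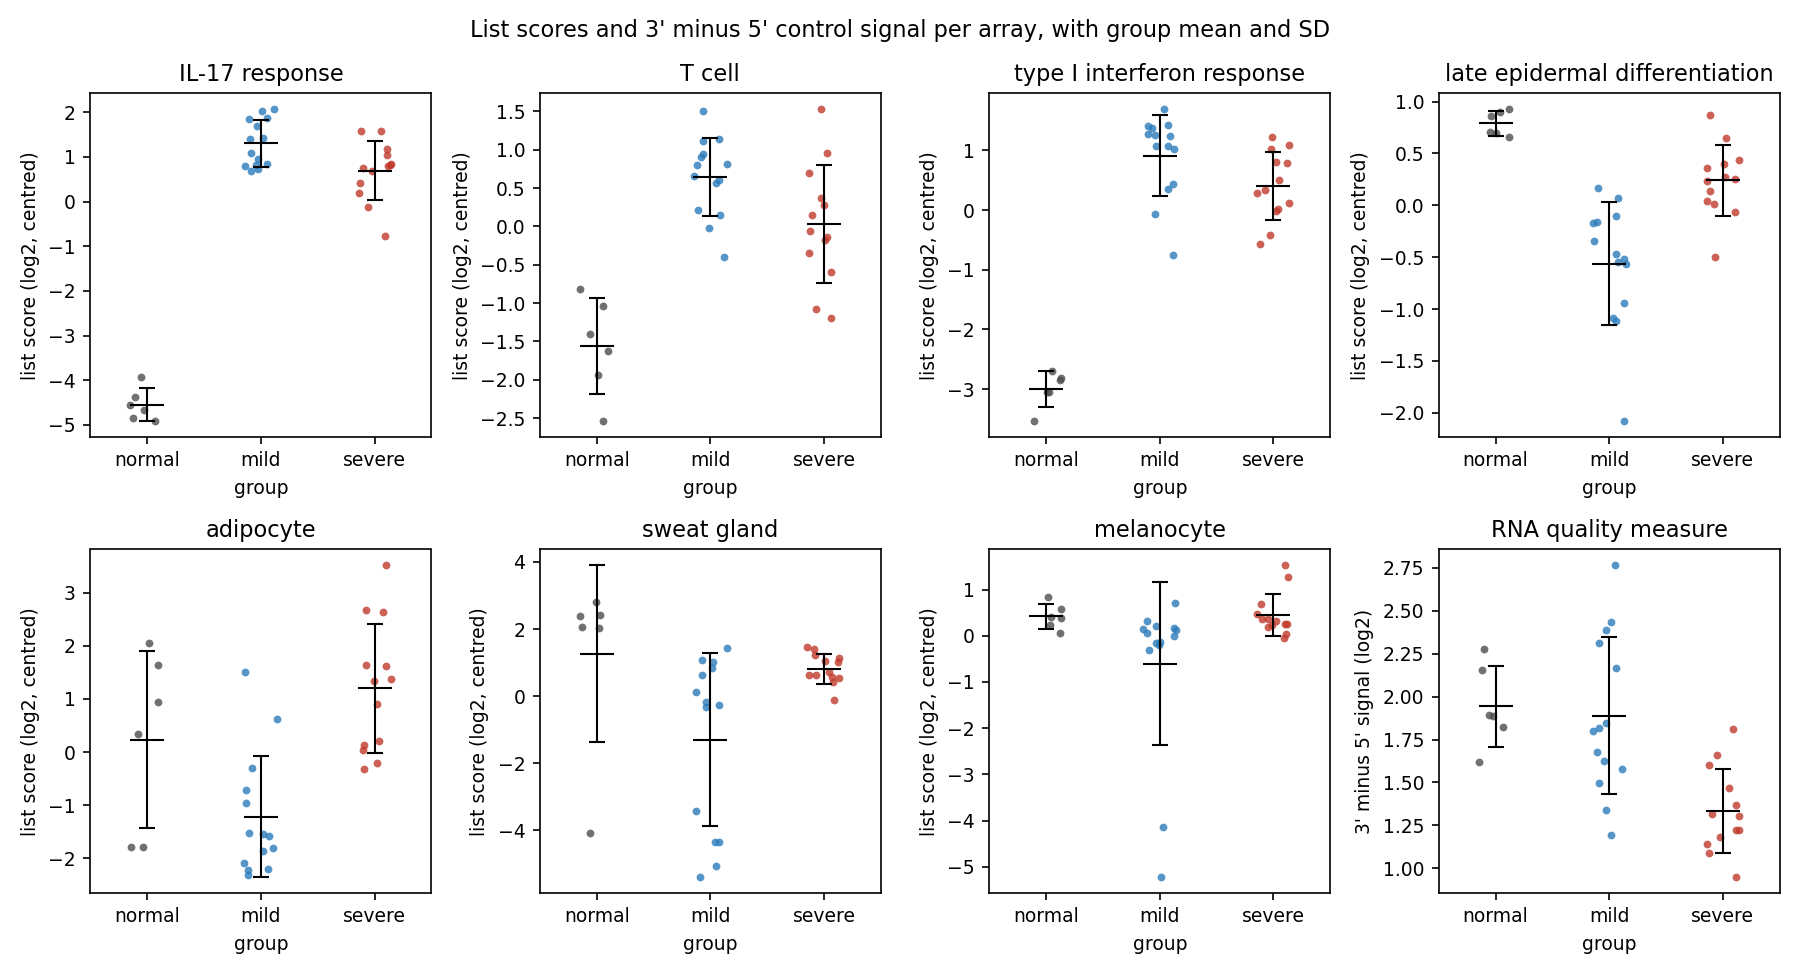
Panels give the score of 7 gene lists (y axis, mean of the centred log2 values of the members) and the 3' minus 5' control signal (log2) on every array by group (x axis), with the group mean and SD. The control signal averages 1.94 in normal skin, 1.89 in mild and 1.33 in severe lesions, and 11 mild arrays lie below the lowest severe array in the adipocyte score.

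The RNA quality measure and the fat content moved with the grade. The 3' minus 5' difference was 0.556 lower in severe than in mild lesions (-0.556, permutation p = 0.00071, adjusted p = 0.00106 over 3 comparisons). With this measure as a covariate limma called 2099 genes between the grades, 1764 of them shared with the 4304, and 44 of the 61 named genes called in this comparison stayed called, IL17A, IL19, IL24, ICOS and CD69 among them, while IL17F (-0.93, adjusted p = 0.141), CD3E (-0.91, 0.105), PIP (1.44, 0.489), SCGB2A2 (1.18, 0.598) and SCGB1D2 (1.51, 0.415) did not. In 12 of the 17 lost calls the fold stayed within 1.5 times its size. The other named genes that lost the call with RNA quality were CCR7, CDC20, CDH19, CXCR2, ELN, ISG15, KIT, LMOD1, MX2, TIGIT, VSIG4 and VSIR. With the adipocyte score as a covariate 1518 genes were called and 18 of the 61 stayed: CASP14, CD6, CNKSR2, CXCL13, FBLN1, IL12RB2, IL17A, IL24, IL4R, IRF7, KLHDC7B, LCK, LGR5, NCAM1, OCA2, PAOX, TSPAN8 and VSIR. In 29 of the 43 calls lost with the adipocyte score the fold stayed within 1.5 times its size, and in 12 it was unchanged or larger, for example CD69 (-0.78) and RHCG (-1.19), so a lost call is not by itself a smaller difference. With both covariates 523 genes were called and 7 of the 61, of which CNKSR2, IL24, CASP14 and OCA2 were called in each of the 3 fits. CXCL1 (-2.00, adjusted p = 0.0724), CXCL8 (-1.31, 0.124) and TNC (-0.94, 0.0703), the rest of the 7, were not called with the adipocyte score alone. With both, IL17A stood at -1.74 (adjusted p = 0.0666), ICOS at -1.45 (0.0998) and CD69 at -0.97 (0.119). No muscle, nerve, blood, sebaceous, hair follicle, endothelial, stress keratin, lipid synthesis or immediate-early list was called between the grades (camera adjusted p = 0.0922, 0.143, 0.65, 0.107, 0.305, 0.771, 0.445, 0.413 and 0.427), but the sebaceous gland list was called higher with RNA quality (median 0.74, adjusted p = 0.0142) or the adipocyte score (0.55, 0.0194) as a covariate.

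Within each lesional group, 3 pairs of list scores were correlated over arrays, 6 relations in all with permutation p-values. The checkpoint and regulatory T cell score followed the T cell score in mild (r = 0.919, adjusted p = 9e-05, Spearman rho = 0.899, adjusted p = 0.00042) and severe lesions (r = 0.914, adjusted p = 9e-05, rho = 0.879, adjusted p = 0.00057), and r was 0.837 and 0.830 without the 2 arrays farthest from the median. The T cell score and the IL-17 response gave no relation that passed in mild lesions (r = -0.242, p = 0.405, rho = -0.284, p = 0.324), and r turned to 0.199 without the 2 farthest arrays (p = 0.529). In severe lesions r was 0.558 (p = 0.0468, adjusted p = 0.0936, rho = 0.445, p = 0.129), which fails the adjustment and fell to 0.447 without the 2 farthest arrays (p = 0.166). The cell cycle score and the IL-17 response gave r = -0.0106 in mild lesions (p = 0.971, rho = 0.187, p = 0.522), and 0.249 without the 2 farthest arrays (p = 0.425). In severe lesions r was 0.320 (p = 0.29, rho = 0.253, p = 0.406), becoming 0.711 without the 2 farthest arrays (unadjusted permutation p = 0.0118). With RNA quality regressed out of both scores, this last relation was 0.309 in mild and 0.0918 in severe lesions. That of T cell and IL-17 response was then -0.301 and 0.468, and that of checkpoint and T cell 0.918 and 0.902.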

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

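Chosen only after the results were seen were the test of dilution, which compares the epidermal lists with the immune genes, the share on the sweat gland score, the separate tests of RNA quality on adipocyte and on sweat gland genes, the restriction of the search for single distant arrays to genes not wholly at the floor in normal skin, and the correlation within 9 mild arrays; the other tests reported in this part were fixed before. The share tests were first run with stricter bounds on the error. They were set back to the rule written beforehand once the values were known. That turned some of them from open to argued against and the test of T-cell content from open to a fit. Under the stricter bounds the shares on the adipocyte and sweat gland scores would be open. So would the share of the immune genes on RNA quality.

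A single array lay far from the rest of its group, by Dixon's ratio of its gap to the range, for 14 of 135 genes and list scores tested in normal skin, where chance gives about 6.75. The items tested are the scores and the genes kept for the text, a choice made after values were seen. The 14 values are not independent, since several come from the same structures. The sweat gland score (ratio 0.887) and its genes PIP (0.974), SCGB2A2 (0.934) and SCGB1D2 (0.849) were far lower on 1 of the 6 normal arrays than on the other 5, where PIP lay between 13.8 and 14.1. PM20D1 (0.746), TNFRSF4 (0.645), KLRB1 (0.657), SOCS1 (0.665) and the neutrophil score (0.633) also had a single low normal array. CTLA4 (0.831), IL23A (0.732), CXCL9 (0.713), FN1 (0.784) and FLG2 (0.635) had a single high one. The sweat gland and neutrophil scores were both lowest on normal replicate 6. That array also correlated least with its group (median r = 0.947). For CTLA4 the high array was normal replicate 2.

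Labels drawn by chance are an unlikely source of the number of genes called in each comparison. Of 100 splits of the arrays, the labels' own included, 1 gave as many genes as the labels for mild against normal (8711, against 4943 for the highest other split), 1 for severe against normal (7513 against 2693) and 1 for severe against mild (4304 against 1). Over 100 genes were called by 4 other splits for mild and 3 for severe against normal. A draw of 100 splits cannot show a chance below 1 in 100. Splits do not test unrecorded handling that follows the groups.

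The first pattern is the large number of genes that differ between severe and mild lesions. A difference in fat or in sweat gland tissue as the whole cause is argued against, since the slopes within the groups account for a median share of 0.0832 ± 0.0942 (adipocyte score) and 0.0945 ± 0.0857 (sweat gland score) of the fold change, where 0.8 was needed, although both lie under the bound of 0.2 only narrowly. For RNA quality the share was 0.167 ± 0.0934, which is far from 0.8 but reaches past 0.2, so a part played by RNA quality stays open. RNA quality and the adipocyte score differ between the grades and cannot be told apart from the grade by the count alone, which was 523 with both as covariates. The grade of disease itself, and any unrecorded difference in handling, stay open.

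The second pattern is that immune and IL-17 response genes were lower in severe lesions. For the 33 genes called lower in 6 immune lists, the slope on RNA quality accounted for a median share of -0.0743 ± 0.196, which argues against RNA quality as the whole cause. Under the stricter bound on the error this verdict would be open. Dilution of the lesion by fat or gland as the whole cause was taken to lower epidermal genes alike. The median of 28 epidermal genes lay 0.551 ± 0.165 (log2, SE) above that of all 99 measured members of the 6 immune lists, at 0.09 against -0.46. That passes the bound set for arguing against dilution, but the epidermal lists themselves change with the disease. Late differentiation genes, lower in mild lesions, rose between the grades (median 0.68), while the stress keratin list stood at -0.10. The gap therefore cannot decide on dilution. Set against only the 33 genes called lower the gap was 0.981 ± 0.215, which their selection widens. Fewer or less active immune cells in the severe lesions stay a hypothesis that was not tested, and dilution stays open beside it. The macrophage and monocyte (median 0.22) and MHC class II (0.11) lists were not lower there. The dendritic cell (-0.22) and cytotoxic and NK cell (-0.38) lists were, though none of these lists was called. The severity of the disease, its duration and the place of the biopsy were not separated here.

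The third pattern is the rise of 16 called adipocyte and sweat gland genes in severe lesions. RNA quality accounted for a share of 0.0694 ± 0.137 over all 16, but its parts differed: for adipocyte genes the share was -0.0665 ± 0.116, which argues against RNA quality as the whole cause, while for sweat gland genes it was 0.66 ± 0.285, so that RNA quality cannot be told apart from the grade there. Deeper biopsies may raise both structures together, but over the severe arrays the 2 scores correlated at r = 0.196 (permutation p = 0.523, rho = 0.0385, p = 0.906), and at 0.161 without the 2 farthest arrays. Over all mild arrays the scores rose together, past the 0.5 that the prediction named. The sweat gland score falls there into sets of 5 and 9 arrays, so no r over all is given. As seen only afterwards, the 5 low arrays also had the lowest adipocyte scores of the mild group, at -1.87 or below. The other 9 lay at -1.81 or above. Within the 9, r was -0.0263 (permutation p = 0.945, rho = -0.217, p = 0.58) and -0.708 without the 2 farthest. These 9 cover only the upper part of the sweat gland score, so their r cannot argue against deeper biopsies. Biopsy depth or body site as a source therefore stays open, and no biological explanation was tested.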

How the results depend on the processing

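Chosen after the data were seen were the fits without the array of each group that stands apart, the fits with the adipocyte score as a covariate, alone or with RNA quality, the gene lists without each normal array, and the tests of ACTB and GAPDH alone; all other alternatives were fixed before.

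The counts of called genes against normal skin stayed within 1.5 times under all alternatives run, from 6529 to 9150 for mild and from 5787 to 8400 for severe lesions. Leaving out each normal array in turn gave 8199 to 8604 genes for mild and 7011 to 7443 for severe lesions. Without the array of each group that stands apart (normal replicate 6, mild replicate 6 and severe replicate 8) the counts were 8193, 6999 and 4422. Between the grades, 4304 genes became 2099 with RNA quality as a covariate, 1518 with the adipocyte score and 523 with both, and 2433 at an adjusted p under 0.01, a stricter threshold by construction. Covariates that differ between the grades take up part of the difference and widen its error, and whether the calls ended for that reason was not tested. Genes changed in both grades fell from 6315 to 2109 where 2-fold changes were required in both, and to 4360.5 with the normal arrays split.

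Of 32 list calls 4 remained with an estimated correlation, 26 with RNA quality as a covariate (5 gained), 28 with the probe set of largest SD and 26 with the adipocyte score, and none reversed. Leaving out each normal array kept 27 to 32 of the 32 list calls. Between the grades fry did not keep the camera calls of the cell cycle (adjusted p = 0.0524) and fibroblast (0.0975) lists. It added calls for the regulatory ligands, the IL-23 and IL-17 cytokines, interferon-gamma and Th1, and nerve (0.0103). Without the 2 farthest arrays, the relation of T cell and IL-17 response scores in severe lesions fell to r = 0.447. That of cell cycle and IL-17 response rose to 0.711. With RNA quality regressed out of both scores the 2 relations stood at 0.468 and 0.0918. The cause was not tested. The RNA quality calls held with ACTB or GAPDH alone.

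Of 4712 alternative results for the 125 genes of the text, 4457 kept direction and side of the threshold, 231 lost the call, 16 gained it and 8 reversed; over all 208 genes the rule allowed these were 6511, 516, 34 and 18 of 7079. The 125 were chosen after these results were seen, so the counts over 208 are the fairer ones. With the sebaceous gland score GAL turned to 1.12 (mild) and 0.11 (severe) and PM20D1 to 0.25 (severe). GAL is part of that score, so the covariate takes up its change by construction. With RNA quality and the adipocyte score together, the severe minus mild differences of ADIPOQ (-0.35), PLIN1 (-0.28), PIP (-1.64), SCGB2A2 (-1.70) and SCGB1D2 (-1.42) turned negative, none past the threshold. ADIPOQ and PLIN1 are part of that score; for the others the cause was not tested. Of the 61 named genes called between the grades, 61 kept the call with quantile normalization, 57 with the probe set of largest SD, 55 with a rank test and 47 with the T cell score.

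No paired analysis was possible because the replicate numbers follow the order of the samples and pair no arrays. Signal over background limits low genes: at the floor of normal skin, folds of cytokines such as IL17A and IL26 are only bounds.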

Other observations

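The test of T-cell content reported here was fixed before the result was seen, but its label was set back to the rule written beforehand, from a stricter one, after the value was known.

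Some gene groups moved without the uniformity of the inflammatory lists. Lipid synthesis was mixed in lesions, with 5 of 13 genes higher and 1 lower in mild and 6 higher and 1 lower in severe lesions against normal skin. Endothelial genes likewise moved both ways, although SELE, an adhesion molecule of activated endothelium, was 2.19 ± 0.46 (log2, SE) higher in mild and 1.98 ± 0.47 higher in severe lesions, in 14 of 14 and 13 of 13 arrays, although neither was called with the sebaceous gland score as a covariate (1.29, adjusted p = 0.078, and 1.27, 0.0623). Of the Schwann cell and nerve list, SOX10 was lower by 2.23 ± 0.35 and CDH19 by 2.24 ± 0.34 in mild lesions, and CDH19 was 1.01 ± 0.27 higher in severe than in mild lesions (12 of 13 arrays, adjusted p = 0.00491), a call lost with RNA quality (0.91, adjusted p = 0.0629) or the adipocyte score (0.29, 0.574) as a covariate.

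Within the mast cell list KIT was lower by 1.08 ± 0.19 and HPGDS by 2.11 ± 0.38 (log2, SE) in mild lesions, in 14 of 14 arrays. Among neutrophil genes FCGR3B, a receptor found nearly only on neutrophils, was higher by 2.11 ± 0.50 in mild and 2.66 ± 0.51 in severe lesions, while AQP9, which other skin cells also express, was lower by 3.72 ± 0.52 and 3.04 ± 0.52. The macrophage receptor CSF1R was lower by 1.06 ± 0.25 and 1.20 ± 0.25 in the 2 grades.

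The checkpoint and regulatory T cell list was not called between the grades (camera adjusted p = 0.296), with 3 of 13 members lower and 1 higher in severe lesions, so the test of T-cell content bears on its median and not on a called change of the list. With the T cell score as a covariate the median severe minus mild difference of the 13 list members went from -0.38 to -0.07, a ratio of 0.191 ± 0.348, where a ratio under 0.25 was set in advance as the value that fewer T cells would give. The error spans values above 0.25, so the shrinkage is consistent with a difference in T-cell content but does not establish it, and checkpoint genes are themselves made by T cells.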
